A study of Danio rerio with 5 samples.

How the data were processed

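RNA was measured by sequencing in 5 libraries of sorted zebrafish cells: 2 of embryonic periderm, 2 of embryonic basal precursors and 1 of adult fin basal cells. Groups and replicate numbers came from the sample titles. Per the labels' protocols, cells were sorted on a SONY SH800S into lysis buffer, RNA was extracted with the RNeasy Plus Micro Kit, and libraries were made with an MGIEasy WES rapid library preparation kit. Strand use, read length and the treatment of reads with several alignments are not given in the sources used here. Reads from a gene and its antisense partner, and from near-identical copies such as the hsp70 genes, therefore cannot be told apart in these counts.

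The counts are whole numbers of reads per transcript row as the authors deposited them, without normalization. Per the submitters' processing notes, HISAT2 2.2.1, featureCounts 2.0.3 and the genome build GRCz11 were used. The RPKM values, which the authors normalized to row length and library total per the file headers, served only to recover each library's total, which lay within 1% of the sum of the row counts. TPM values in the same table were not used here. The table had 75805 transcript rows for 30849 gene symbols. Isoforms stood in separate rows, and reads were counted in more than 1 of them: of 6655 adjacent isoform groups over 50 counts, 57.8% held rows with identical counts. Of the gene symbols, 5962 had rows in more than 1 place, krt4 and tp63 among them. A further 57 rows had names that a spreadsheet had turned into dates, of which 46 were matched to a symbol by accession. Gene names came from the table, and the accession matches from a RefSeq table of the assembly GRCz12tu, used for names alone. No coordinates are printed because the table gives none.

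For each gene symbol, the row with the highest mean count over the libraries represented the gene, so that reads shared by isoforms of a gene were counted once. Alternatives chosen after the data were seen were the sum of all rows of a gene, the sum over places of 1 representative row each and, for the adult position, leaving out the genes of the cell type lists. Tests used edgeR 4.0.16 in R 4.3.3, with filterByExpr by group, TMM scaling, estimateDisp, glmQLFit and glmQLFTest, Benjamini-Hochberg adjustment and a threshold of 0.05. Standard errors were the absolute log2 fold change divided by the square root of the F statistic. The embryonic comparison was fitted on the 4 embryonic libraries without a replicate block, and 15589 genes were tested. Both adult comparisons were fitted on all 5 libraries with 18147 genes, the spread coming from the embryonic libraries. CPM values are TMM-scaled over 5 libraries. TMM factors were 1.19, 1.18, 0.961 and 1.19 in the embryonic periderm and basal libraries and 0.620 in the adult library, in which the 10 most abundant genes took 23.9% of gene counts. Where a group had 0 counts, the fold is a bound against 3 counts per library, averaged over the libraries of the group. With 1 to 3 counts the fold is a ratio with a 95% Poisson interval on the lower count, pooled over the group.

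Before the data were examined, 30 gene lists and a rule for named genes were fixed. The lists covered basal identity, hemidesmosome, basement membrane, fibrillar collagen, periderm identity, tight junction, desmosome, cortical actin, secretory, cell cycle, ribosomal protein, respiratory chain, mitochondrial genome, glycolysis, embryonic RNA-binding and chromatin, Notch, Wnt, fin fold, Hox, antigen presentation, heat-shock and immediate-early, and keratin genes. Markers of ionocytes, leukocytes, mesenchyme, pigment cells, muscle, neural cells, blood and vessels, and hatching gland and yolk made up the rest. Name patterns caught 25 genes that are no members of their lists, and these were removed after the names were seen. Lists with at least 5 tested genes (29 of them) were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2, with a preset correlation of 0.01. The estimated correlation and fry were alternatives. The rule named krt4, itgb4, tp63 and krtt1c19e. It added the 8 genes per direction with the largest absolute log2 change among those past the threshold with at least 20 CPM in the higher group, no overlap between libraries and a symbol that is no clone or accession name. From each list it took up to 4 called members per direction with at least 10 CPM, or, where none was called, up to 2 by mean CPM as values. Fewer were named where the text would have repeated itself, and the result of 1 gene is not reported here.

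Alternatives fixed in advance were RLE scaling, total counts without a factor, no filter beyond 1 count, a filter of 5 CPM in 2 libraries, thinning to the shallowest library, leaving out each embryonic library, DESeq2 1.42.0, edgeR's older quasi-likelihood fit, a test against a 2-fold change, the replicate block and a fit of all 5 libraries. Simulated counts with 200 genes changed were tested with the same code. In the embryonic comparison (15589 genes), 16.4% of 4-fold changes (log2 change of 2) and 78.8% of changes of 4 on the log2 scale were recovered, with 3 false among 66 calls. In the comparison of adult with embryonic basal cells (18147 genes), the shares were 7.5% and 56.1%, with 6 false among 49 calls.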

Results

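The data were 5 RNA-seq libraries of fluorescence-sorted zebrafish epidermal cells. Periderm is the outer layer of the embryonic skin, and basal cells form the layer that sits on the basement membrane. Embryonic periderm cells were sorted by a krt4 reporter (2 libraries) and embryonic basal precursors by an itgb4 reporter (2 libraries), both 1 day after fertilization. The adult basal cells, also sorted by the itgb4 reporter, came from the caudal fin and made 1 library. The deposited row counts summed to 7976968 and 12975986 in embryonic periderm replicates 1 and 2, and to 9451663 and 8831154 in embryonic basal replicates 1 and 2. The adult library held 5580007. With 1 transcript row kept per gene, the totals were 4622901, 7505595, 5522942, 4904833 and 3521991 in the same order. A floor of 3 counts then corresponded to between 0.338 and 0.565 CPM in the embryonic libraries and to 1.37 CPM in the adult library, and such floors cover counting error only. The labels do not say whether replicates came from separate clutches, so p-values measure only the spread between these samples, which may be technical. The periderm and basal reporters were carried by different transgenic lines, and the adult cells differed from the embryonic ones in both age and body site.

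The embryonic comparison asked whether basal precursors already differed from periderm cells at 1 day. itgb4, which encodes the hemidesmosome integrin used for the sort, was 18.7-fold higher in basal precursors (log2 fold change 4.23, SE 0.68, adjusted p = 0.0251), at 492 ± 6.84 CPM (SD, n = 2) against 25.5 ± 22.5 CPM in periderm (SD, n = 2). krt4, the periderm keratin used for the other sort, was abundant in both populations, at 45760 ± 20820 CPM in periderm and 21060 ± 4049 CPM in basal precursors (SD, n = 2 each), and this difference did not pass the test (log2 fold change -1.14, SE 0.69, adjusted p = 0.466). tp63, the transcription factor of basal keratinocyte identity, measured 206 ± 16.9 CPM in basal precursors and 46.4 ± 28.1 CPM in periderm (SD, n = 2 each; log2 fold change 2.12, SE 0.48, adjusted p = 0.0601). That difference passed in 6 of 16 alternative settings (adjusted p between 0.00178 and 0.238), among them those without periderm replicate 2 (adjusted p = 0.0418) and without basal replicate 2 (adjusted p = 0.0465). The basal keratin krtt1c19e measured 1635 ± 1040 and 1718 ± 1240 CPM (SD, n = 2 each; adjusted p = 0.977).

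**Figure D1:**
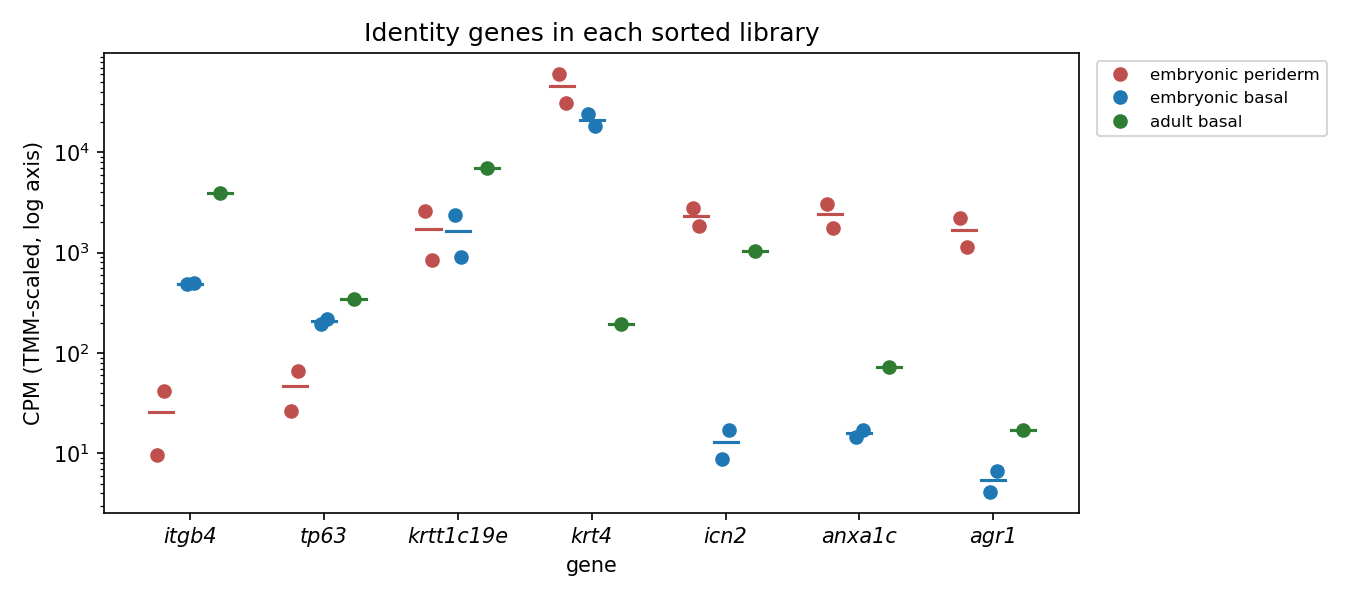
TMM-scaled CPM on a log axis for 7 genes, with 1 point per library and a bar at each group mean (2 embryonic periderm, 2 embryonic basal and 1 adult basal library). itgb4 lay at 9.65 and 41.4 CPM in periderm, 487 and 497 CPM in embryonic basal precursors and 3905 CPM in the adult library, while krt4 lay between 18200 and 60490 CPM in the 4 embryonic libraries.

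Most called periderm genes were lower in basal precursors. agr1, an anterior gradient gene and 1 of 2 called among 17 members of the secretory list, was 312-fold lower (log2 fold change -8.29, SE 0.62, adjusted p = 0.00306), from 1682 ± 778 CPM in periderm to 5.41 ± 1.78 CPM in basal precursors (SD, n = 2 each). The periderm markers icn2, anxa1c, cldne and krt1-19d were 180.2-fold, 154-fold, 100.4-fold and 80.9-fold lower, with adjusted p of 0.00306, 0.00306, 0.00306 and 0.00335. Of the 29 tested members of the periderm identity list, 13 were lower and 2 higher over all genes, and 15 were lower and 4 higher adjusted over the list alone. The list's median log2 fold change was -1.14 (camera adjusted p = 5.55e-05; adjusted p = 0.497 with an estimated correlation). The 2 members that went the other way were spaca4l (7.25-fold higher, adjusted p = 0.0195) and krt8 (4.57-fold higher, adjusted p = 0.0432), a keratin of simple epithelia. Losses of the krt8 call included edgeR's older quasi-likelihood fit (adjusted p = 0.059) and transcript rows summed (adjusted p = 0.0761). It held in 8 of 16 alternative settings, and the spaca4l call in 14. Both calls were lost without periderm replicate 1 (adjusted p = 0.181 and 0.284) and without periderm replicate 2 (adjusted p = 0.0697 and 0.143), and that of krt8 also without basal replicate 1 (adjusted p = 0.166; range over 16 alternatives 2.95e-07 to 0.181 for spaca4l and 3.26e-04 to 0.284 for krt8).

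Single scaffold genes of the desmosome and cornified envelope were also lower in basal precursors. The plakin family genes evplb, evpla and ppl were 158-fold, 30.9-fold and 25.2-fold lower, with adjusted p of 0.00306, 0.00824 and 0.00757. tgm1, a transglutaminase that cross-links cornified envelope proteins, had no counts in the basal libraries and 33.2 ± 21.6 CPM in periderm (SD, n = 2), at least 61.5-fold lower against a floor of 3 counts per library. In the desmosome list 5 of 16 members were lower over all genes and the same number adjusted over the list alone, with a median of -0.27 and a mean of -2.20 (camera adjusted p = 0.0155; adjusted p = 0.497 with an estimated correlation). In the tight junction list 5 of 27 members were lower over all genes, and 7 were lower and 4 higher adjusted over the list alone. Among them, oclnb was 54.4-fold and cldnf 28.8-fold lower (adjusted p = 0.00418 and 0.00831), while the list did not pass camera (adjusted p = 0.397; adjusted p = 0.666 with an estimated correlation), with a median of 0.00 and a mean of -0.74. The connexin gene cx30.3 and cmah, which makes a sialic acid form, were at 0 counts in basal precursors, at least 45.5-fold and 65.2-fold lower than in periderm. vstm5, duox and arl11 each had 1 count in the basal libraries. Their levels in periderm were 469-fold (95% counting interval 84.2 to 18540), 378-fold (67.8 to 14920) and 377-fold (67.6 to 14870) above that count. The calls for tgm1, cx30.3 and cmah were lost without periderm replicate 1 (adjusted p = 0.0866, 0.115 and 0.0955), and over 16 alternatives their adjusted p lay between 5.04e-08 and 0.115.

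Most tested genes of the basement membrane, fibrillar collagen and hemidesmosome lists had positive log2 fold changes in basal precursors (34 of 40, 18 of 21 and 12 of 15), but few passed the test singly. The 8 largest higher genes of the fixed rule were grem1b, itgb4, serpinh1b, rbp4, lbx1a, foxi1, csf1b and kcnh2a, from 18.8-fold for grem1b, a secreted BMP antagonist (adjusted p = 0.00831), to a log2 fold change of 3.86 for kcnh2a, a potassium channel gene (adjusted p = 0.0240). serpinh1b, the collagen chaperone, was 17.8-fold higher with uneven basal libraries, 6993 and 1158 CPM (adjusted p = 0.0443). It passed in 7 of 16 alternative settings, and its log2 fold change lay between 2.36 and 4.94 without 1 library. rbp4, the retinol carrier, was 16.3-fold higher (adjusted p = 0.0128). In the basement membrane list 2 of 40 members were higher over all genes and 10 adjusted over the list alone. Among them, tinagl1 was 8.53-fold higher (adjusted p = 0.0126). That list had a median of 1.11 (camera adjusted p = 9.84e-07; adjusted p = 0.497 with an estimated correlation). In the fibrillar collagen list 2 of 21 members were higher and 1 lower over all genes, and 14 were higher and 2 lower adjusted over the list alone, with a median of 1.51 (camera adjusted p = 4.42e-05; adjusted p = 0.497 with an estimated correlation). Its matrix protein genes fn1b and postnb had log2 fold changes of 2.54 and 2.41 (adjusted p = 0.0395 and 0.0351), and the cartilage and notochord collagen col2a1a was 9.45-fold lower (adjusted p = 0.0258). The basal identity list had 1 of 16 members higher over all genes and 4 adjusted over the list alone, with a median of 1.28 (camera adjusted p = 3.63e-04, and adjusted p = 0.497 with an estimated correlation). The member called over all genes was itgb4, whose reporter defined the sort, so that call is no independent sign of basal identity. The hemidesmosome list had 2 of 15 members higher over all genes, and 5 higher and 1 lower adjusted over the list alone, with a median of 0.76 (camera adjusted p = 0.00105; adjusted p = 0.497 with an estimated correlation). Its higher members included itgb4. Each call for a gene named in this paragraph was lost without periderm replicate 1 (adjusted p between 0.0571 for csf1b and 0.296 for serpinh1b), in a fit with 1 residual degree of freedom. The log2 fold changes kept their direction, which the choice of genes called on the same libraries made likely. In that fit the higher genes lay between 2.08 for postnb and 4.57 for csf1b, against 2.41 for postnb and 3.86 for csf1b, and col2a1a lay at -2.81. Without periderm replicate 2, the calls for serpinh1b, rbp4, lbx1a, foxi1, tinagl1 and postnb were lost (adjusted p between 0.0528 and 0.157), and without basal replicate 1 those for serpinh1b, lbx1a, foxi1, fn1b, postnb and col2a1a (adjusted p between 0.0510 and 0.115; range over 16 alternatives for the genes of this paragraph 4.72e-11 to 0.296).

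Markers of other cell types also differed between the sorted populations. Mesenchyme markers moved with the matrix genes: col6a2, col6a1 and lum were 11.4-fold, 9.87-fold and 8.38-fold higher in basal precursors (adjusted p = 0.0170, 0.0138 and 0.0176). In that list 4 of 24 members were higher over all genes and 11 adjusted over the list alone, with a median of 1.22 (camera adjusted p = 1.48e-08; adjusted p = 0.497 with an estimated correlation). Markers of pigment cells, blood, neurons and leukocytes moved with the periderm genes. The pigment cell regulator gene mitfa had 1 count in the basal libraries, and its periderm level was 173-fold above it (95% counting interval 31.1 to 6833). The pigment cell genes aox5, gch2 and pmela had log2 fold changes of -3.96, -3.93 and -3.82 (adjusted p = 0.0426, 0.0112 and 0.00818). The red blood cell gene alas2 had 0 basal counts and was at least 19.6-fold lower (adjusted p = 0.0296). slc4a1a and hbbe1.1 were 18.4-fold and 18.2-fold lower (adjusted p = 0.0103 and 0.0151), with near-identical globin copies making the share of hbbe1.1 uncertain. The neuronal gng3 was 8.25-fold lower (adjusted p = 0.0407). The leukocyte list genes mfap4 and lcp1 were 48.4-fold and 38.8-fold lower (adjusted p = 0.0221 and 0.00919). lcp1 is also in the cortical actin list, so its call is no sign of leukocytes alone. The mfap4 call was lost with transcript rows summed (adjusted p = 0.0557, range over 16 alternatives 7.25e-11 to 0.0557). Over all genes, 7 of 17 pigment, 7 of 22 blood and vessel, 7 of 32 neural and 5 of 17 leukocyte members were lower. Adjusted over the list alone, the lower counts were 15, 12, 20 and 10, and 1 neural and 1 leukocyte member were higher. The medians were -3.71, -2.32, -1.82 and -3.62, the last -2.92 with genes at 0 counts placed at their bound. The camera adjusted p were 1.94e-10, 1.01e-06, 1.48e-08 and 5.67e-06, and each list had adjusted p = 0.497 with an estimated correlation. Hatching gland markers included he2, the hatching enzyme, 62.2-fold lower (adjusted p = 0.00306). Skeletal muscle transcripts took 3.25% and 8.41% of gene counts in periderm replicates 1 and 2, and 2.88% and 7.16% in basal replicates 1 and 2. The calls for col6a2, col6a1 and lum were lost without periderm replicate 1 (adjusted p = 0.0834, 0.0893 and 0.166) and without periderm replicate 2 (adjusted p = 0.0603, 0.0586 and 0.0702), and those for aox5, gch2, pmela, alas2, slc4a1a, hbbe1.1 and gng3 without periderm replicate 1 (adjusted p between 0.0567 and 0.225). The calls for aox5 and alas2 were also lost without periderm replicate 2 (adjusted p = 0.113 and 0.0807), and those for aox5, alas2 and gng3 without basal replicate 1 (adjusted p = 0.0566, 0.0776 and 0.147; range over 16 alternatives for these genes 7.93e-12 to 0.225). The muscle list did not pass the test (median -0.13, camera adjusted p = 0.914; adjusted p = 0.987 with an estimated correlation).

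**Figure D2:**
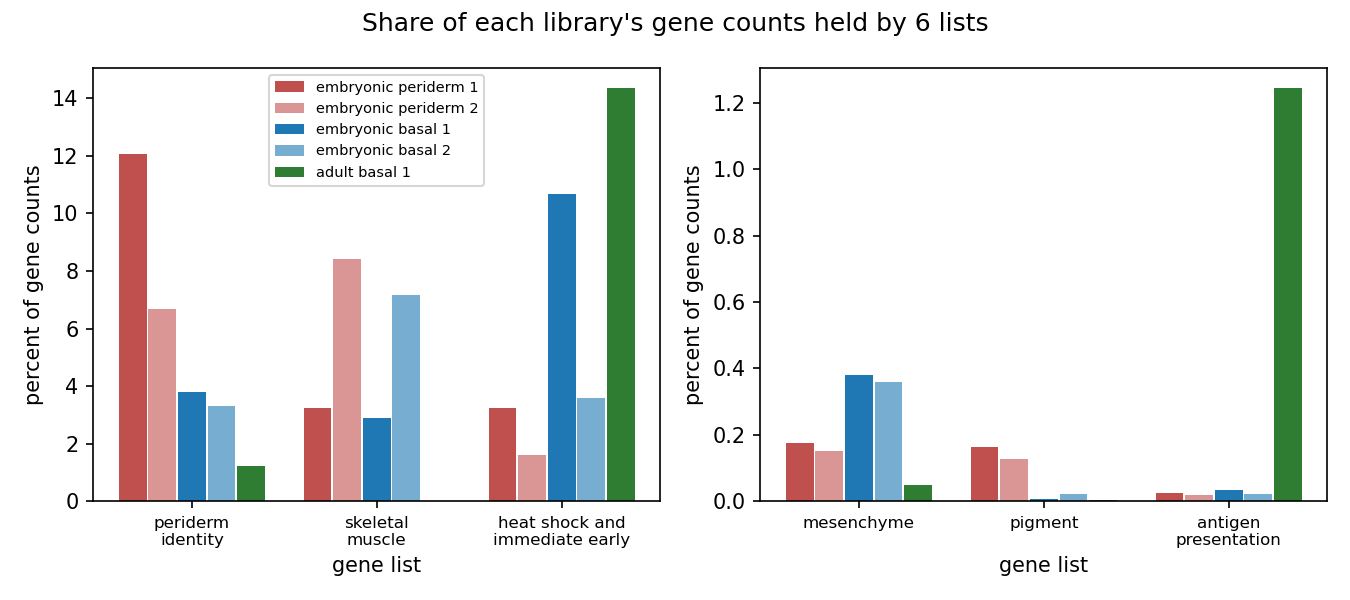
Percent of each library's gene counts held by 6 gene lists, with 1 bar per library from 0 and the lists of larger share in the left panel. Skeletal muscle took between 2.88% and 8.41% in the 4 embryonic libraries and 0.000% after rounding in the adult library, and the heat-shock and immediate-early list ranged from 1.60% to 14.4%.

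Heat-shock and immediate-early genes, which cell dissociation can induce, differed between replicates. The list took 10.7% and 3.57% of gene counts in basal replicates 1 and 2, and 3.24% and 1.60% in periderm replicates 1 and 2. hsp70.1 measured 26950 and 6780 CPM in the basal libraries and 8081 and 3460 CPM in periderm (adjusted p = 0.366), and near-identical hsp70 copies make its share of reads uncertain. The list had no member past the edgeR threshold among 41, against 13 higher at an unadjusted p under 0.05 and 10 by DESeq2. Its median was 1.11 (camera adjusted p = 6.23e-04; adjusted p = 0.659 with an estimated correlation). Of the cell cycle genes, pcna measured 575 ± 5.82 CPM in basal precursors and 807 ± 246 CPM in periderm (SD, n = 2 each; adjusted p = 0.573). The median over 39 cell cycle genes was -0.39 (camera adjusted p = 0.0507, or 0.0474 with total counts alone; adjusted p = 0.816 with an estimated correlation).

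In total, edgeR's quasi-likelihood test called 545 of 15589 genes between the embryonic populations, 149 higher and 396 lower in basal precursors, with a median absolute log2 change of 3.87. The count was 1396 with DESeq2, 349 with edgeR's older quasi-likelihood fit, 220 against a 2-fold change and 208 with transcript rows summed. The count moved when single libraries were left out, which leaves 1 residual degree of freedom. Without periderm replicate 1, 78 genes were called, none of them higher by edgeR (932 higher at an unadjusted p under 0.05), and 384 by DESeq2, 143 higher and 241 lower. It was 293, 197 and 948 without periderm replicate 2, basal replicate 1 and basal replicate 2. In each of these fits the 149 higher and 396 lower genes had the same direction, with medians without periderm replicate 1 of 2.37 and -4.30 against 2.47 and -4.62. These genes were called on the same libraries, so a kept direction was largely fixed by that choice and is no separate check. The calls for agr1, icn2, anxa1c, cldne, krt1-19d, oclnb, cldnf, evplb, evpla, ppl, vstm5, duox, arl11, mitfa, lcp1, apodb and he2 held in each of 16 alternative settings, while the higher calls named above, itgb4 included, were lost without periderm replicate 1 (itgb4 adjusted p = 0.0740; also lost with transcript rows summed, adjusted p = 0.0610; range over alternatives 4.31e-10 to 0.0740).

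The comparison of adult with embryonic basal cells used the single adult library, which was assumed to vary like the 4 embryonic libraries. Single basal attachment genes and the keratin gene krt15 were higher in the adult library. itgb4 was 7.94-fold higher, at 3905 CPM against 492 ± 6.84 CPM (SD, n = 2; log2 fold change 2.99, SE 0.74, adjusted p = 0.0245). The hemidesmosome collagens col17a1b and col17a1a were 695-fold and 99.9-fold higher (adjusted p = 5.83e-04 and 0.00216), krt15, a keratin of basal stem cells, 215-fold (adjusted p = 7.13e-04) and the plakin gene dst 49.0-fold (adjusted p = 0.00114). krt4 was 107-fold lower, at 196 CPM (log2 fold change -6.74, SE 1.38, adjusted p = 0.0127). tp63 stood at 346 CPM in the adult library and 206 ± 16.9 CPM in embryonic basal cells (SD, n = 2; adjusted p = 0.366), and krtt1c19e at 6945 and 1635 ± 1040 CPM (SD, n = 2; adjusted p = 0.102).

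Of the basal identity list, 8 of 16 members were higher over all genes, and 8 were higher and 1 lower adjusted over the list alone, with a median of 2.04 (camera adjusted p = 0.00255; adjusted p = 0.549 with an estimated correlation). Of the hemidesmosome list, 8 of 15 members were higher and 2 lower by both adjustments, over all genes and adjusted over the list alone (median 2.89, camera adjusted p = 0.00743; adjusted p = 0.662 with an estimated correlation). Across all tested genes the median log2 fold change was -0.59 with TMM scaling, -0.39 with RLE scaling and -1.38 with total counts alone, and list medians are to be set against it. The desmosome list had 11 of 16 members higher and 1 lower by both adjustments, including adjusted over the list alone. In that list tgm5l, a transglutaminase gene at 0 embryonic basal counts, was at least 233.5-fold higher. dsg2.1, a desmosomal cadherin, was 37.8-fold and the transglutaminase gene tgm1l1 25.5-fold higher (adjusted p = 0.00190 and 0.00112), and the plakophilin gene pkp3b was lower, with 1 adult count and a ratio of 152-fold (95% counting interval 27.3 to 6011). The list median was 3.76, or 3.38 with genes at 0 counts placed at their bound (camera adjusted p = 2.78e-05; adjusted p = 0.419 with an estimated correlation). Of the tight junction list, 5 of 29 members were higher by both adjustments, including adjusted over the list alone, and cldna was 50.7-fold higher (adjusted p = 0.00308; list median 1.02, camera adjusted p = 0.00209; adjusted p = 0.419 with an estimated correlation).

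In the basement membrane list most called genes were lower. Among the higher ones, the laminin chain gene lamb2l was 50.7-fold higher (adjusted p = 0.00318). nid1a, which encodes the linker protein nidogen, fbln2 and the laminin chain gene lama4 had 0 adult counts, at least 213-fold, 62.9-fold and 62.9-fold lower against a floor of 3 counts in the adult library. Over all genes, 14 of 40 members were lower and 2 higher, and adjusted over the list alone 20 were lower and 2 higher. The median was -3.18, or -2.62 with genes at 0 counts placed at their bound (camera adjusted p = 0.00466; adjusted p = 0.747 with an estimated correlation). Mesenchyme markers were lower in the same library: 15 of 25 over all genes and 18 adjusted over the list alone, with meox1 and cxcl12b at 0 counts, at least 69.7-fold and 68.6-fold lower. That list's median was -6.24, or -3.51 with genes at 0 counts placed at their bound (camera adjusted p = 1.08e-06; adjusted p = 0.311 with an estimated correlation).

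Keratin and periderm genes split. krt93, at 0 embryonic basal counts, was at least 24.6-fold higher, a call lost with DESeq2 (adjusted p = 0.242) and with transcript rows summed (adjusted p = 0.0524; range over 13 alternatives 0.0153 to 0.242). krt5 and krt91 were 45.0-fold and 37.7-fold higher in adult cells, at 30930 and 14120 CPM (adjusted p = 0.00601 and 0.00204). The embryonic keratins cyt1 and cyt1l were 731-fold and 250.4-fold lower (adjusted p = 0.00254 and 0.00368), and the near-identity of these copies makes the share of each uncertain. Over all genes 6 of 18 keratins were higher and 5 lower, and adjusted over the list alone 8 were higher and 7 lower; with total counts alone 5 were higher and 7 lower over all genes. Of the periderm identity list, 10 of 29 members were higher and 4 lower over all genes, and 13 higher and 5 lower adjusted over the list alone (median 0.96, camera adjusted p = 0.0202; adjusted p = 0.673 with an estimated correlation). Its higher members included klf4, a transcription factor of differentiating keratinocytes (112-fold, adjusted p = 0.00109), icn (91.5-fold, adjusted p = 0.00114) and icn2 (80.7-fold, adjusted p = 0.00115). With total counts alone, 6 members of that list were higher and 7 lower.

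Proliferation genes were lower in adult cells. Over all genes 33 of 39 cell cycle genes were lower, and 34 adjusted over the list alone, with a median of -3.92, or -3.89 with genes at 0 counts placed at their bound (camera adjusted p = 1.65e-10; adjusted p = 0.600 with an estimated correlation). bub1ba, a spindle checkpoint gene, had 0 adult counts and was at least 9.15-fold lower. mcm3, a subunit of the replicative helicase, was 106-fold lower (adjusted p = 0.00182), rrm2 had 2 adult counts and a ratio of 231-fold (95% counting interval 64.0 to 1908), and plk1 had 1 adult count and a ratio of 238-fold (42.7 to 9400). The embryonic RNA-binding protein genes igf2bp1, igf2bp3 and lin28a had 0 adult counts, at least 374-fold, 139-fold and 67.1-fold lower. In their list 10 of 28 members were lower and 1 higher by both adjustments, including adjusted over the list alone. That list did not pass camera (median -2.42, or -0.54 with genes at 0 counts placed at their bound; adjusted p = 0.140; adjusted p = 0.594 with an estimated correlation).

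Immune genes were higher in the adult library. cd44a, the hyaluronan receptor, was at 1199 CPM in the adult library and at 0 counts in embryonic basal cells, at least 2224-fold higher against a floor of 3 counts per library. The chemokine gene ccl27b, with 1 count in the embryonic basal libraries, was at 3686 CPM in the adult library, a ratio of 41120-fold (95% counting interval 7380.0 to 1624000). cd74a, the MHC class II invariant chain, had 2 embryonic basal counts and 3149 adult CPM, a ratio of 17560-fold (4862 to 145000). The chemokine gene ccl19a.2, the receptor gene tnfrsf18 and the chemokine gene ccl19b were at least 429-fold, 406-fold and 395-fold higher. The other large increases were those of aste1 and crispld2, each with 1 embryonic basal count. Their ratios were 11920.0-fold (2140.0 to 471000) and 10660.0-fold (1913 to 421000), at 1069 and 955 adult CPM. Of the antigen presentation list, 20 of 27 members were higher over all genes and 22 adjusted over the list alone, with a median of 5.80 (camera adjusted p = 9.61e-12; adjusted p = 0.311 with an estimated correlation), and the immunoproteasome gene psmb8a was at least 245-fold higher. Leukocyte markers moved with them: 15 of 25 were higher over all genes and 18 adjusted over the list alone, with a median of 4.26, or 3.46 with genes at 0 counts placed at their bound (camera adjusted p = 3.07e-09; adjusted p = 0.311 with an estimated correlation). The leukocyte list genes LOC100151049 and ptprc measured 26.5 and 20.1 CPM in the adult library, and the whole list took 0.110% of its gene counts, against 0.049% and 0.036% in embryonic basal replicates 1 and 2.

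Stress-response and glucose-use genes were among the higher lists. In the heat-shock and immediate-early list 21 of 41 members were higher and 1 lower over all genes, and 27 higher and 1 lower adjusted over the list alone (median 2.57, camera adjusted p = 2.27e-08; adjusted p = 0.662 with an estimated correlation). dusp2, a MAP kinase phosphatase, was 164-fold and fosb 54.0-fold higher (adjusted p = 0.00102 and 0.00243), and the list took 14.4% of adult gene counts against 10.7% and 3.57% in embryonic basal replicates 1 and 2. The glucose transporter gene slc2a1b and the pyruvate kinase gene pkma were 63.9-fold and 20.6-fold higher (adjusted p = 0.00238 and 0.00114). aldoab was at 0 adult counts, at least 953-fold lower, and gapdh had 3 adult counts, a ratio of 967-fold (95% counting interval 331 to 4687). In replicates 1 and 2, aldoab stood at 943 and 2059 CPM in periderm and 958 and 1660 CPM in embryonic basal cells. gapdh stood at 904 and 1615 CPM and at 899 and 1756 CPM. Skeletal muscle transcripts were likewise higher in replicates 2, and whether the embryonic counts of both genes came from basal cells was not tested. Of 29 glycolysis genes 9 were higher and 3 lower by both adjustments, including adjusted over the list alone, and the list's median of 0.86 and its camera direction were positive while its mean was -0.14 (camera adjusted p = 0.0115; adjusted p = 0.419 with an estimated correlation). With total counts alone, 4 glycolysis genes were higher and 4 lower, with a median of 0.11.

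The skeletal muscle list had the lowest median of the 29 lists tested between adult and embryonic basal cells. actc1a, tpma, mylpfa, myl1, acta1b and mylz3, which encode actins, tropomyosin and myosin light chains, had 0 adult counts, between at least 1963-fold lower for actc1a and at least 1176-fold lower for mylz3. Tenascin gene tnw was at least 1101-fold lower. All 30 members of the muscle list were lower, over all genes and adjusted over the list alone, and 24 of them had 0 adult counts. The median was -13.70 as fitted and -8.30 with those genes at their bound (camera adjusted p = 1.04e-13; adjusted p = 0.567 with an estimated correlation). Neural markers had 14 of 32 members lower over all genes, and 20 lower and 1 higher adjusted over the list alone, with elavl3 at least 99.2-fold lower (median -6.50, or -2.43 at the bounds; camera adjusted p = 2.78e-05; adjusted p = 0.662 with an estimated correlation). Blood and vessel markers had 12 of 28 members lower and 2 higher over all genes, and 14 lower and 2 higher adjusted over the list alone (median -7.30, or -2.74 at the bounds; camera adjusted p = 0.00356; adjusted p = 0.662 with an estimated correlation).

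**Figure D3:**
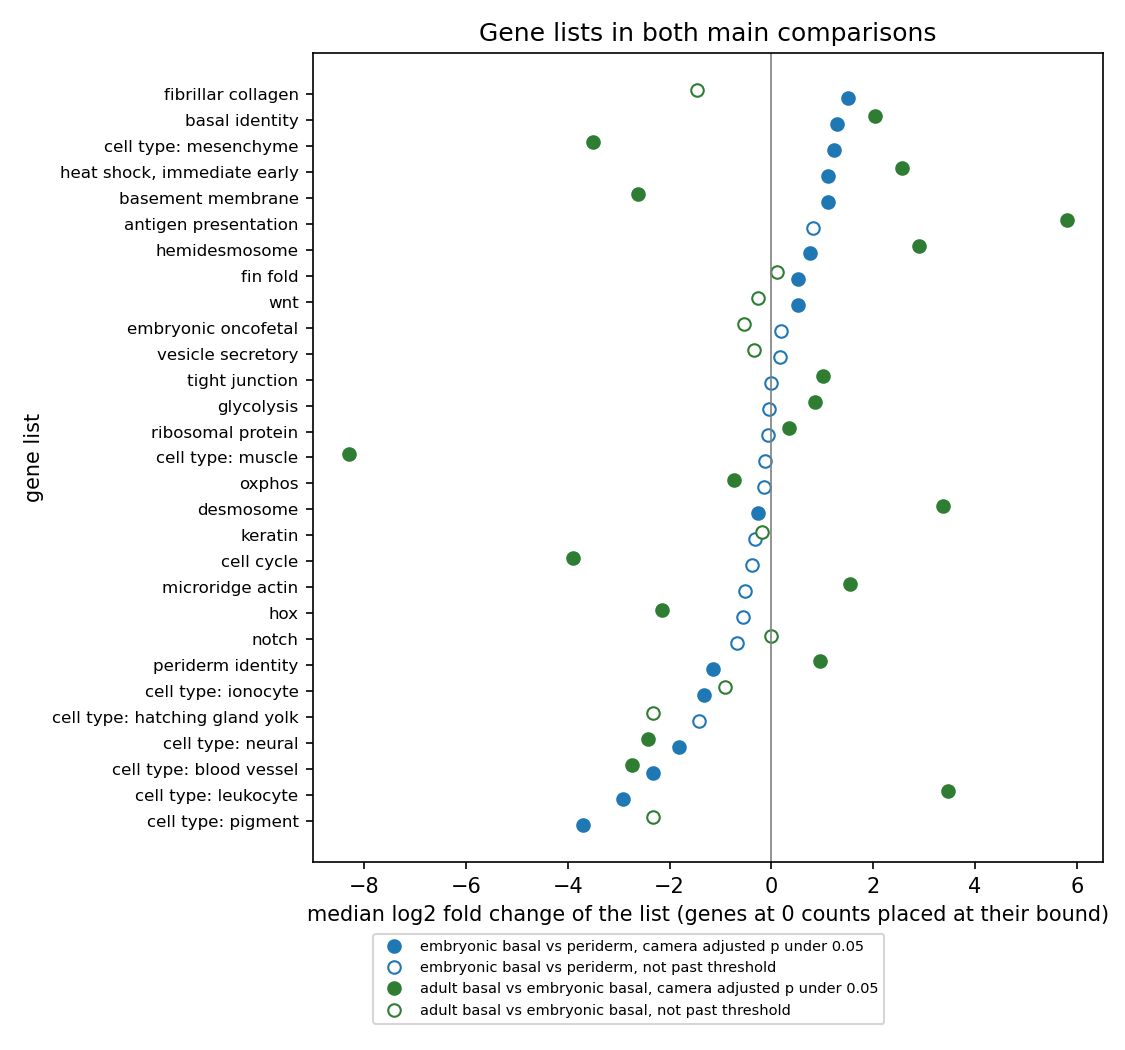
Median log2 fold change of 29 gene lists in both main comparisons, with genes at 0 counts placed at their bound, and filled points where camera with a preset correlation passed adjusted p 0.05. Periderm identity lay at -1.14 between the embryonic populations and at 0.96 between adult and embryonic basal cells, basement membrane at 1.11 and -2.62, and none of the lists passed with an estimated correlation.

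In total, 4186 of 18147 genes were called between adult and embryonic basal cells, 2110 higher and 2076 lower, with the single adult library assumed to vary like the embryonic ones. The split was 2452 higher and 1812 lower with RLE scaling and 1507 higher and 3890 lower with total counts alone, and 2780 genes passed a test against a 2-fold change. The itgb4 call was lost without embryonic basal replicate 1 (adjusted p = 0.0631; range over 14 alternatives 5.98e-04 to 0.0631), and the krt4 call without periderm replicate 1 or 2 (adjusted p = 0.115 and 0.143; range 6.00e-23 to 0.143).

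Adult basal cells were also set against embryonic periderm, to place the adult profile relative to both embryonic populations. Of 18147 genes 5199 were called, 2585 higher and 2614 lower in the adult library, which was again assumed to vary like the others. The median log2 fold change over all genes was -0.72 with TMM scaling, -0.59 with RLE scaling and -1.66 with total counts alone. The split was 2771 higher and 2382 lower with RLE scaling and 1793 higher and 5134 lower with total counts alone. Across genes, the log2 CPM of the adult library correlated with embryonic basal replicates 1 and 2 at Pearson r of 0.584 and 0.507, and with periderm replicates 1 and 2 at 0.441 and 0.457 (18147 genes, which are not independent replicates; Spearman rho 0.573, 0.508, 0.439 and 0.467).

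Of the 545 genes that separated the embryonic populations, 349 (64.0%) had an adult level on the embryonic basal side of the midpoint between the embryonic group means. Expression-matched random lists gave a median of 53.2% (95% of 10000 lists between 49.2% and 57.4%). Of the genes lower in basal precursors, such as agr1 at 16.9 and anxa1c at 72.3 adult CPM, 274 of 396 (69.2%) lay on the basal side, against 58.8% in random lists (54.0% to 63.6%). The periderm markers icn2 and icn, at 1045 and 10710 adult CPM, lay on the periderm side. A gene at 0 adult counts falls on the side of the lower embryonic group by construction, and the random lists were not matched on adult detection. Of the 274, 152 had 0 adult counts, and 23 were members of the cell type lists, such as gch2 and hbbe1.1. The 23 are no count of all genes from other cell types, since no list covered lens cells, for example. The lens crystallin genes crybb1 and cryba1l1 also lay on the basal side, at -5.63 and -5.56 from the midpoint on the log2 scale. Of the genes higher in basal precursors, such as itgb4 at 3905 and rbp4 at 2622 adult CPM, 75 of 149 (50.3%) lay on the basal side, against 38.3% in random lists (30.9% to 45.6%). grem1b, lbx1a, foxi1 and kcnh2a, also higher in basal precursors, were among 32 such genes with 0 adult counts, of which 0 lay on the basal side. The overall share was 63.2% with genes of the cell type lists left out, an alternative chosen after the data were seen, and 71.9% with total counts alone (82.3% of the genes lower and 40.0% of those higher in basal precursors). For the genes higher in basal precursors it was 76.7% without periderm replicate 2, 55.2% without basal replicate 1 and 65.1% without basal replicate 2, and without periderm replicate 1 edgeR called no gene higher. With 1 adult library there is no replicate check on these shares.

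**Figure D4:**
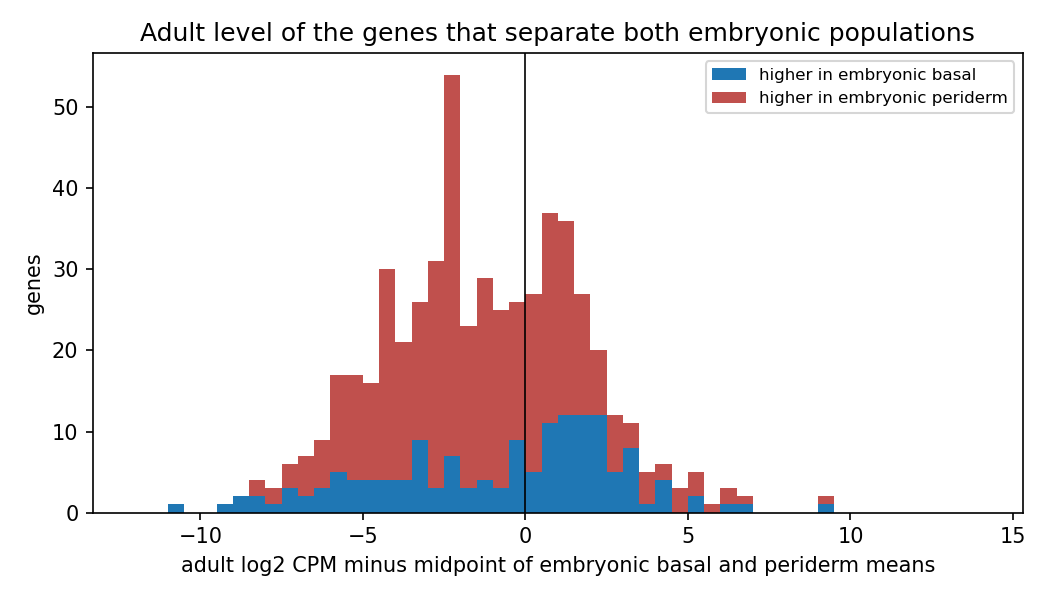
Histogram of adult log2 CPM minus the midpoint of the embryonic basal and periderm means for the 545 genes called between them, stacked by direction. The median lay at 0.08 for the 149 genes higher in embryonic basal cells and at -1.79 for the 396 genes higher in embryonic periderm.

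Genes called against periderm were shared between adult and embryonic basal cells in 67 higher and 234 lower cases. Independent lists of these sizes would share 17.3 and 66.4 of 15583 genes. In opposite directions, 29 genes were higher in embryonic basal and lower in adult cells (24.99 for independent lists) and 14 lower and higher (46.1). Of the 149 genes higher in embryonic basal cells, 63 were lower in adult than in embryonic basal cells (19.9 for independent lists) and 12 higher (13.2), and of the 396 lower genes 96 were higher (35.2) and 32 lower (52.8). These last counts share the embryonic basal libraries with opposite sign, so part of the 63 and the 96 may come from them. For the calls against periderm, counts of all libraries were simulated with no effect, and both comparisons used the same simulated periderm libraries. They shared 0.05 and 0 calls on average over 20 simulations. These counts hold no change to be called, so they give no baseline for the 67 and 234. The correlation of the log2 fold changes was 0.355, against 0.299 in the simulation with no effect, and their covariance was 2.05, against 0.265. Part of the overlap and of the correlation may come from the shared periderm libraries. Part of the lower overlap may also come from other cell types in the periderm sort, whose markers include gch2 and hbbe1.1. That part was not tested, and the use of separate periderm libraries, given next, leaves it in place. With separate controls, chosen after the data were seen, each comparison kept 1 periderm library, assumed to vary like the others. With embryonic basal cells against periderm replicate 1 and adult cells against replicate 2, 13 higher and 134 lower genes were shared (2.32 and 36.4 for independent lists), with a covariance of 1.75 and a correlation of 0.254. With the replicates exchanged, 64 lower genes were shared (11.9), the covariance was 1.77 and the correlation 0.273, and edgeR called no gene higher in embryonic basal cells, so none could be shared (932 at an unadjusted p under 0.05, 143 by DESeq2).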

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

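The 2 ways of adding up transcript rows, the share without cell type markers and the separate periderm controls were chosen after the data were seen; the other alternatives were fixed before. Against 545 calls in the embryonic comparison, 1396 were made with DESeq2 (540 of them shared with the 545), 349 with the older quasi-likelihood fit, 220 against a 2-fold change (a stricter question) and 208 with rows summed, where 203 of the 208 were shared with the 545. Apart from the stricter question, the cause was not tested. Leaving out 1 embryonic library gave between 78 and 948 calls. The adult against embryonic basal count fell from 4186 to 2780 against a 2-fold change and otherwise stayed between 3274 without basal replicate 1 and 5397 with total counts alone. The adult against periderm count lay between 3714 against a 2-fold change and 6927 with total counts alone, and between 3940 and 5773 without 1 library. The share on the basal side was 71.9% with total counts alone and between 62.9% and 75.4% without 1 library, against 64.0%; the cause was not tested. Of 29 lists, 15 and 19 passed camera, 0 and 0 passed with an estimated correlation (2 and 3 at an unadjusted p under 0.05) and 0 and 9 passed fry (9 and 16 unadjusted), not all of them among those past camera, and leaving out 1 library gave 14 to 16 and 17 to 19. Replicate numbers were shared by the embryonic groups but marked no stated clutch or day. The deviations of same-numbered libraries correlated at 0.219 across genes. With a replicate block 584 genes, 16 lists and 62.5% on the basal side were found; tp63 passed (adjusted p = 0.0395), and serpinh1b, fn1b and gng3 did not (adjusted p = 0.0630, 0.0504 and 0.0620). No paired analysis was possible for the adult comparisons because the groups compared share fewer than 2 numbers.

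Among named genes, krtt1c19e changed sign in the embryonic comparison without periderm replicate 1 (log2 fold change 0.96) and without basal replicate 2 (0.46; between -0.92 and 0.96 without 1 library). actc1b (between -0.73 and 0.60) and mt-rnr2 (between -1.75 and 0.39) did so without periderm replicate 2, and actc1b also without basal replicate 1 (0.31). tp63 changed sign between adult and embryonic basal cells with total counts alone (-0.059). None of these passed the threshold, and the cause was not tested. Of the other results for single genes, 803 in the embryonic comparison and 1085 between adult and embryonic basal cells kept direction and side of the threshold, 114 and 15 lost the call, and 6 and 2 gained it. Small changes went uncalled: no log2 change of 1 was recovered among 67 simulated in the embryonic comparison. Thinning to the shallowest library gave 545 embryonic calls, 499 of them shared with the main calls, so less depth did not lower that count. Greater depth was not tested, and depth limits genes near the floor of 3 counts.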

Other observations

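The tests of explanations in this part were chosen after the results they concern were seen, apart from 1 that was replaced. Hox genes and single fin fold, Notch and Wnt genes differed between adult fin and embryonic basal cells. The posterior Hox genes hoxa13a and hoxa13b were 179-fold and 141-fold higher in the adult library (adjusted p = 5.83e-04 and 0.00106, edgeR), at 84.2 and 339 CPM. The anterior and trunk genes hoxb3a and hoxb8a had 0 adult counts, at least 76.7-fold and 57.3-fold lower. Over all genes 4 of 49 Hox genes were higher and 18 lower, and adjusted over the list alone 6 were higher and 26 lower (median -7.01, or -2.15 with genes at 0 counts placed at their bound; camera adjusted p = 3.75e-04; adjusted p = 0.662 with an estimated correlation). The fin fold transcription factor genes sp9 and sp8a were 49.8-fold and 9.17-fold higher (adjusted p = 0.00233 and 0.00319), msx2b had a log2 fold change of 3.46 (adjusted p = 0.00716), and 7 of 28 fin fold genes were higher and 2 lower (8 and 4 adjusted over the list alone; 5 and 7 with total counts alone). That list's median of 0.11 (-0.68 with total counts alone) and camera direction were positive and its mean was -1.76 (camera adjusted p = 0.448; adjusted p = 0.754 with an estimated correlation). The Notch ligand genes jag2a and jag1b were 26.1-fold and 7.85-fold higher (adjusted p = 0.0103 and 0.00425). Of 26 Notch genes 4 were higher and 8 lower (8 and 8 adjusted over the list alone; median -0.01, or 0.19 with RLE scaling, mean -1.73, camera direction positive, adjusted p = 0.711; adjusted p = 0.793 with an estimated correlation). Of 32 Wnt genes, wnt5a (65.9-fold, adjusted p = 0.00238) and fzd10 (14.3-fold, adjusted p = 0.00183) were among 6 higher and 3 lower (6 and 7 adjusted over the list alone; 3 and 10 with total counts alone; median -0.46, or -0.27 with genes at 0 counts placed at their bound, mean -0.85, camera direction positive, adjusted p = 0.682; adjusted p = 0.754 with an estimated correlation).

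Between the embryonic populations, the Wnt secretion gene wls was 3.45-fold, the chemokine gene cxcl12a 4.96-fold and hoxb6a 6.07-fold higher in basal precursors (adjusted p = 0.0492, 0.0174 and 0.0341, edgeR), and each call was lost without periderm replicate 1 (adjusted p = 0.303, 0.140 and 0.191) and without periderm replicate 2 (adjusted p = 0.145, 0.0758 and 0.0807). The calls for wls and hoxb6a were also lost without basal replicate 1 (adjusted p = 0.210 and 0.107), and over 16 alternatives the adjusted p of the 3 genes lay between 1.34e-05 and 0.303. The Wnt list (median 0.52, camera adjusted p = 0.0109) and the fin fold list (median 0.52, camera adjusted p = 0.0187) each had 1 member higher over all genes, and 3 higher and 1 lower and 2 higher adjusted over the list alone; both had adjusted p = 0.497 with an estimated correlation. The Hox list had a median of -0.56 (1 higher over all genes, 2 higher and 3 lower adjusted over the list alone; camera adjusted p = 0.397; adjusted p = 0.858 with an estimated correlation). Keratins krt92 and krt17 were 6.70-fold and 6.26-fold lower (adjusted p = 0.0331 and 0.0246), calls lost without periderm replicate 1 (adjusted p = 0.191 and 0.152) and without periderm replicate 2 (adjusted p = 0.0735 and 0.0522; range over 16 alternatives 2.87e-06 to 0.191). Of 17 keratins 3 were lower and 1 higher (4 and 1 adjusted over the list alone; median -0.32, camera adjusted p = 0.285; adjusted p = 0.838 with an estimated correlation). Cortical actin genes (3 of 23 lower and 1 higher, 4 and 3 adjusted over the list alone; median -0.52, camera adjusted p = 0.302; adjusted p = 0.575 with an estimated correlation) did not pass as a list, nor did glycolysis genes (2 of 28 lower, 3 adjusted over the list alone; median -0.04, camera adjusted p = 0.285; adjusted p = 0.497 with an estimated correlation). In the secretory list 2 of 17 genes were lower by both adjustments, including adjusted over the list alone (median 0.17, mean -0.82; camera adjusted p = 0.959; adjusted p = 0.987 with an estimated correlation). In the hatching gland and yolk list 1 of 9 genes was higher and 1 lower (1 and 2 adjusted over the list alone; median -1.43, camera adjusted p = 0.148; adjusted p = 0.497 with an estimated correlation). Ionocyte genes had a median of -1.33 (camera adjusted p = 0.00980; adjusted p = 0.497 with an estimated correlation), with 6 of 13 lower at an unadjusted p under 0.05, 3 lower by DESeq2, 3 lower adjusted over the list alone and none past edgeR's threshold over all genes. Medians were -0.07 for ribosomal protein genes (camera adjusted p = 0.959, direction positive with TMM and negative with total counts alone), -0.15 for respiratory chain genes (0.302), 0.19 for embryonic RNA-binding and chromatin genes (0.458), -0.67 for Notch genes (0.148) and 0.82 for antigen presentation genes (0.440), with estimated-correlation adjusted p of 0.987, 0.858, 0.659, 0.497 and 0.816.

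Other lists between adult and embryonic basal cells were as follows. Ribosomal protein genes had a median of 0.35 (1 of 81 higher and 1 lower; camera adjusted p = 0.00677; adjusted p = 0.747 with an estimated correlation), which was -0.47 with total counts alone, where the list did not pass camera (adjusted p = 0.720). Respiratory chain genes had a median of -0.73, or -0.13 relative to all genes (7 of 85 lower, 1 adjusted over the list alone, and 29 lower with total counts alone; camera adjusted p = 0.0463, or 0.135 with RLE scaling; adjusted p = 0.754 with an estimated correlation). Cortical actin genes had 8 of 25 members higher by both adjustments, including adjusted over the list alone (5 higher and 3 lower with total counts alone; median 1.55, camera adjusted p = 0.00582; adjusted p = 0.419 with an estimated correlation). The keratin list had a median of -0.76, or -0.19 with genes at 0 counts placed at their bound, a mean of -0.24 and a positive camera direction (adjusted p = 0.676; adjusted p = 0.864 with an estimated correlation). Secretory genes (3 of 19 higher and 2 lower, 3 and 3 adjusted over the list alone, 1 and 4 with total counts alone) had a median of -0.35 and a positive camera direction (adjusted p = 0.646; adjusted p = 0.754 with an estimated correlation). Fibrillar collagens had 7 of 22 members lower and 2 higher (8 and 2 adjusted over the list alone; median -1.46, camera adjusted p = 0.140; adjusted p = 0.754 with an estimated correlation). Pigment genes had 3 of 20 lower and 1 higher by both adjustments, including adjusted over the list alone (median -3.23, or -2.32 at the bounds; camera adjusted p = 0.300; adjusted p = 0.754 with an estimated correlation), hatching gland and yolk genes 4 of 15 lower and 2 higher (4 and 3 adjusted over the list alone; median -5.03, or -2.32 at the bounds; camera adjusted p = 0.390; adjusted p = 0.754 with an estimated correlation), and ionocyte genes 1 of 19 higher (median -0.91, camera adjusted p = 0.682; adjusted p = 0.864 with an estimated correlation). For the ionocyte genes, 0 were called adjusted over the list alone, and 0 were higher and 4 lower with total counts alone. The mitochondrial genome list held 2 tested genes, too few for camera, with a median of -1.36 between the embryonic populations and 2.39 between adult and embryonic basal cells. Its gene mt-rnr2, a ribosomal RNA, took 1.40% and 6.13% of gene counts in periderm replicates 1 and 2, 0.970% and 2.48% in basal replicates 1 and 2, and 3.95% in the adult library.

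Non-epidermal markers were present in the embryonic sorts: actc1b, the most abundant of 30 measured muscle genes, was at 10010 and 22630 CPM in periderm and 9950 and 20300 CPM in basal replicates 1 and 2, although both sorts gated on an epidermal reporter. The muscle list shares no gene with another list, and the adult library held 16 counts over all of it, with no gene at 10 CPM. Muscle cells or their RNA carried into the sorts are a candidate source. The SD of the genes' log2 basal to periderm ratios was 0.71 for replicates 1 and 0.43 for replicates 2, against 1.02 and 0.73 over 7490 genes. The last value also lay under the bound set for the test, so replicates 2 separate little. The 7490 genes were not matched to the muscle genes on abundance. Reporter activity in muscle cells could leave an even ratio too, so the SD does not single out this source. A lower share of epidermal cells in the periderm libraries, if it raised each other cell type alike, would leave all 6 lists lower in basal precursors. Of these, 5 had a negative median, that of muscle only -0.13. The mesenchyme list went against it: 22 of 24 genes were higher in basal precursors, with a lower quartile of 0.76. Cell types need not enter both sorts in equal proportion, so this list cannot exclude a lower epidermal share. Reporter activity outside the epidermis and the different lines remain open and untested.

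krt4 was abundant in embryonic basal precursors, at 46.0% of its periderm level. Periderm cells or their RNA in the basal sort would bring their other abundant transcripts in the same ratio. Of 18 further periderm list genes at 100 CPM or more in periderm, 8 lay below 0.1 of krt4's ratio, among them icn2 at 0.559%, anxa1c at 0.657% and cldne at 1.00%, which argues against carried-over periderm as the whole source. cyt1 and cyt1l were at 46.5% and 37.1%. Reads shared between the places at which krt4 is annotated were not examined, and expression of early keratins by basal precursors, a difference the design allows, stays open and untested.

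Heat-shock and immediate-early genes were high in the adult library. A few genes taking most of the counts would shift all other genes by a common factor, which leaves no excess of a list over all genes. The list's median exceeded that of all genes by 3.17 to 3.18 on the log2 scale under 3 scalings. A common factor alone would not leave that excess, which rests on the single adult library. The comparison was recorded as unable to tell, and no further verdict on the explanation is drawn from it. The 3 scalings are no separate checks, since they move all genes alike and cannot change that excess. An earlier test, with its bound written before its result, left the list out of the library totals and kept 21 of 21 higher calls, but it too moved no value and was replaced once that was seen. Stress during dissociation and sorting, unequal between libraries, may contribute: between the embryonic basal libraries, sorted by the same reporter but with muscle shares of 2.88% and 7.16%, the median absolute log2 difference of the list was 1.80, against 0.56 over all genes, and 37 of 41 genes were higher in replicate 1, although differences in cell mixture were not separated from stress. Age and body site are confounded with the adult library and stay open as untested.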
